A study of Mus musculus with 8 samples.

How the data were processed

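RNA was measured by sequencing in 8 mouse pancreas samples, all from mice given repeated injections of cerulein, a peptide that overstimulates the exocrine pancreas and brings on acute pancreatitis. Per the labels, 4 samples came from mice with Anxa1 deleted in myeloid cells and 4 from mice with intact floxed Anxa1 alleles. They are called CKO1 to CKO4 and WT1 to WT4 here, after the group and the replicate number in each title. The labels do not say whether the replicates were separate animals, so every p-value measures the spread between samples. Total RNA was extracted and sequenced on an Illumina instrument. The reference build was mm10, as given in the submitters' processing notes. The aligner, the read counter, the annotation and any filter are not given in the sources used here.

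The deposited table held 16888 genes by symbol and 8 named value columns, 1 per sample, with no unit in its header. The values were deposited as RPKM, read numbers divided by the length of the gene and by the total reads of the library. This unit was read from the numbers themselves. Of the 16068 genes above 0 in at least 2 libraries, 16056 (99.93%) had a gene length at which every value was a whole number of reads, within 0.05 reads, once multiplied by that length and by the total of its library. Whether the authors counted reads or read pairs is not given in the sources used here. The other 12 of these genes are described with the results, and another 820 genes were above 0 in 1 library at most. A last, unnamed column held 8 numbers and was not used in any comparison. No fold changes or p-values of the authors were analysed here, and the table held 0 mitochondrially encoded genes.

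The library totals recovered in this way ran from 30469002 to 34359802 reads, and the recovered reads of the genes made up 99.95% or more of each total. A count of 3 reads on a gene of 1 kb corresponded to 0.087 to 0.098 RPKM, and counts below that were treated as too few to show a level. Floors of this kind cover counting error only.

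The comparison was planned for read counts, with a switch to limma if the table held normalized values. It held RPKM, so limma 3.58.1 was run in R 4.3.3 on log2 of RPKM plus a pseudocount of 1. Genes with at least 1 RPKM in at least 4 libraries were tested (8513 genes), with group as the only term, a mean trend and robust empirical Bayes variances. Benjamini-Hochberg adjustment ran over all tested genes with a threshold of 0.05. Log2 changes and SE are those of log2(RPKM + 1), so they are smaller than the ratio of means for genes near 1 RPKM, and folds are ratios of mean RPKM. The recovery, the exact tests and the plots used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9. Gene positions are from GENCODE M21.

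In all, 33 gene lists for cell types, inflammatory and stress processes and technical effects were written before the data were examined, together with the test, the first set of other settings and the choice of genes to name. The 26 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, each adjusted over the lists. Values given for fry are those for a shift in 1 direction, unless its mixed test, which counts changes either way, is named. Members past the threshold were counted over all genes and adjusted over the list alone. The rule for named genes took Anxa1, the 10 higher and 10 lower genes with the largest log2 change among those past the threshold with a mean of at least 1 RPKM and no overlap between the groups, and the up to 4 members of each list with the smallest unadjusted p. Predicted genes and gene segments were counted but not named. A few genes, among them 1 of the 10 lower genes, are not reported here. Genes named outside that rule are said to be so. The share of reads from acinar enzymes was compared with an exact two-sided permutation test over 70 arrangements.

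The settings written beforehand were a pseudocount of 0.1, no filter on low values, a filter at 1 CPM (a count scaled to the library total), variances without a trend, limma-voom on the recovered reads, the replicate number as a block, and leaving out each library in turn. Median centring, totals without acinar enzymes, removal of a trend on gene length, leaving out the 12 genes without whole reads, and replacing their values were added after the data were seen. The comparison was also run on each of the 35 splits of the 8 libraries into 4 and 4.

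The steps were tested on simulated data. Of 100 planted changes in simulated tables, the recovery found 98, with 0 unchanged values called, and returned all 8 totals exactly. In a simulated limma run with the same number of libraries, 11.9% of genes planted at a 1.5-fold change, 80.6% of those at 2-fold and 98.5% of those at 4-fold passed the threshold. In that run 6 unchanged genes passed (4.51% of calls), and 0 lists passed where none had been changed. Genes were simulated independently of each other, with an assumed spread. In the data the members of a list varied together, with an estimated correlation of up to 0.871 (MHC class II). The run therefore does not show how often lists pass wrongly in the data.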

Results

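The data were gene expression levels in whole pancreas from 8 cerulein-treated mouse samples, 4 with a myeloid deletion of Anxa1 (CKO) and 4 floxed controls (WT). The library totals recovered from the RPKM values were 34201941, 34359802, 34126009 and 31584517 reads in CKO1 to CKO4, and 31841533, 32112760, 31219289 and 30469002 reads in WT1 to WT4. Reads of the genes in the table made up 99.95% or more of each, so the number of reads sequenced is not known. The question was how the pancreas transcriptome in acute pancreatitis differs when myeloid cells lack annexin A1, a phospholipid-binding protein that restrains inflammation. Levels are given as mean RPKM ± SD with n = 4 per group, and log2 changes as CKO minus WT with their SE.

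Anxa1 (chromosome 19, 20373428 to 20390944, minus strand of mm10) was measured first. Its level was 4.84, 4.76, 5.21 and 7.13 RPKM in CKO1 to CKO4, and 8.44, 14.7, 7.05 and 9.74 RPKM in WT1 to WT4. The mean was 5.48 ± 1.11 RPKM in CKO and 9.98 ± 3.33 RPKM in WT, a log2 change of -0.73 (SE 0.19, adjusted p = 0.0417), with the lowest WT library just below the highest CKO library. The tissue kept Anxa1 transcripts in every CKO library, and the table does not tell which cells made them. The call held without CKO4 or WT3 but missed the threshold without CKO1, CKO2, CKO3, WT1, WT2 or WT4. Over all 8 omissions the log2 change ran from -0.86 to -0.54 and the adjusted p from 0.0358 to 0.108. The threshold was also missed with no filter on low values (0.0932), limma-voom (0.0595), median centring (0.0958), totals without the acinar enzymes (0.071) and the length trend removed (0.0641).

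The 10 higher genes named here were those with the largest log2 change among genes past the threshold with a mean of at least 1 RPKM and no overlap between the groups. Hbegf, a ligand of the EGF receptor, rose 6.54-fold (22.6 ± 6.6 against 3.45 ± 1.48 RPKM; log2 change 2.44, SE 0.26, adjusted p = 0.000433). Egr1, an immediate early transcription factor, rose 4.84-fold (42.5 ± 2.55 against 8.77 ± 0.583 RPKM; log2 change 2.15, SE 0.10, adjusted p = 3.09e-07). Gdf15, a stress-induced cytokine, rose 9.96-fold, from 0.365 ± 0.11 to 3.64 ± 0.512 RPKM (log2 change 1.76, adjusted p = 3.8e-06). Fgf21, a metabolic hormone induced by cell stress, rose from 1.92 ± 0.749 to 22.9 ± 20.1 RPKM (log2 change 2.73, SE 0.52, adjusted p = 0.0235), with 52.1 RPKM in CKO1 and 7.32 RPKM in CKO4. Gadd45a, a growth arrest and DNA damage response gene, rose 4.53-fold, Klf6 3.09-fold, the amino acid transporter Slc38a2 3.15-fold, Wfdc2 4.91-fold, Ppp1r15a, which reverses the translation block of the stress response, 2.91-fold, and the MAP kinase phosphatase Dusp1 2.81-fold. The call of Fgf21 was lost without CKO2 (adjusted p = 0.0684), WT1 (0.0749), WT2 (0.0784), WT3 (0.0634) or WT4 (0.0622).

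Among the genes that fell, the largest log2 change was that of Crct1, at 0.949 ± 0.411 RPKM in CKO against 6.63 ± 0.983 RPKM in WT (log2 change -1.98, SE 0.16, adjusted p = 1.9e-05). Arg1, the arginine-degrading enzyme of alternatively activated macrophages, was at 1.04 ± 0.152 against 6.39 ± 3.25 RPKM (log2 change -1.72, SE 0.33, adjusted p = 0.018). Id2, an inhibitor of basic helix-loop-helix factors, fell from 23.7 ± 1.94 to 7.14 ± 1.56 RPKM (log2 change -1.62, SE 0.14, adjusted p = 4.27e-05). Nr1d1, a core clock repressor, fell from 28.8 ± 6.93 to 10.1 ± 3.24 RPKM (log2 change -1.45, adjusted p = 0.00642). Gadd45g (-1.71), the sterol sensor Insig1 (-1.54), Tcim (-1.50) and the lipid droplet gene Hilpda (-1.42) fell as well. So did the histone gene H1f2, from 218 ± 6.57 to 70.4 ± 8 RPKM (log2 change -1.62, SE 0.11, adjusted p = 3.8e-06). Whether reads of related histone genes were counted with it was not tested. Arg1 missed the threshold without CKO2 (adjusted p = 0.0528), WT1 (0.0516) or WT3 (0.0546). The calls of Insig1 and Tcim ended without CKO2, CKO3, WT1, WT2, WT3 or WT4. Their adjusted p then reached 0.11 and 0.108, both without WT2.

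**Figure D1:**
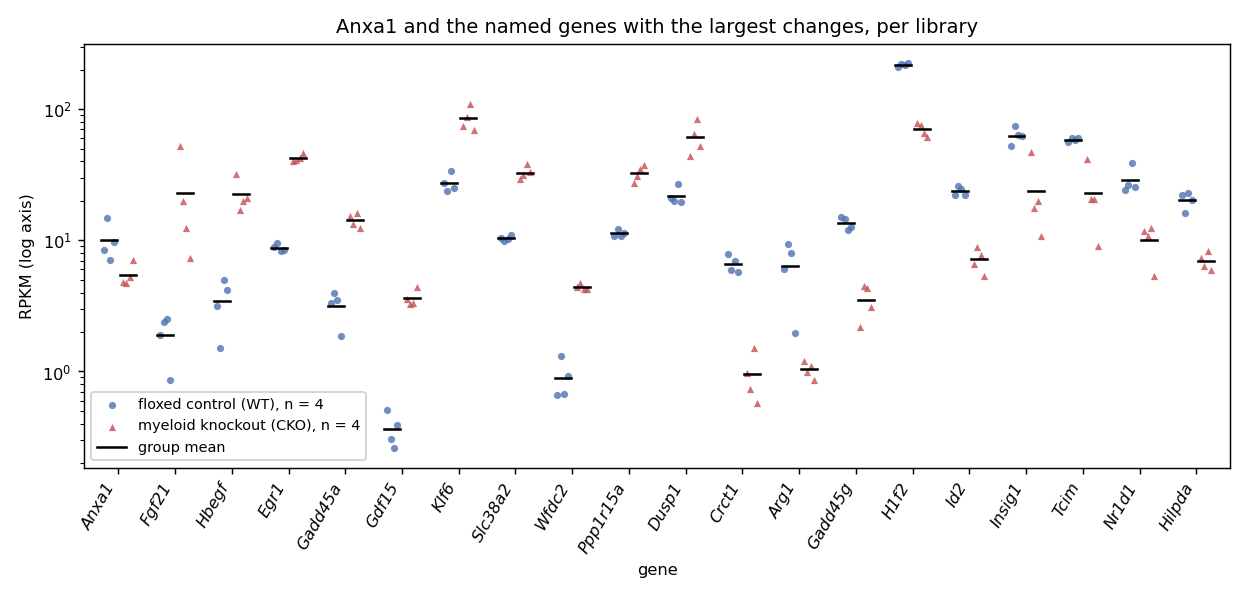
RPKM (log axis) of Anxa1 and of 10 higher and 9 lower genes with large log2 changes, with 1 point per library (circles WT, triangles CKO, n = 4 each) and a black bar at each group mean. Egr1 lay at 40.3 to 46 RPKM in CKO and 8.3 to 9.57 RPKM in WT, while CKO4 overlapped WT for Anxa1 (7.13 against 7.05 RPKM in WT3).

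Across the 8513 tested genes, 610 passed the threshold, of which 121 were higher and 489 lower in CKO. By size, 64 of the 610 changed at least 2-fold, a count that rests on the pseudocount of 1 (142 with a pseudocount of 0.1 and 149 with limma-voom). In all, 2323 genes had an unadjusted p under 0.05. The median log2 change of all tested genes was -0.12, and median centring moved it to -0.01. With that scaling 605 genes passed, 345 higher and 260 lower, and with library totals that left out the acinar enzymes 668 passed, 228 higher and 440 lower, so the balance of higher and lower genes rested on the scaling. The 610 genes became 228 (47 higher) without CKO2, 267 (63 higher) without CKO4, 185 (55 higher) without WT1, 245 (68 higher) without WT2, 297 (87 higher) without WT3 and 254 (59 higher) without WT4, and without CKO1 681 genes passed, 242 of them higher.

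Of the 26 lists tested, 7 passed with the preset correlation, 0 with an estimated correlation and 0 with fry for a shift in 1 direction. The mixed test of fry, which counts changes either way, passed some lists and not others. Its adjusted p ran from 3.55e-08 for immediate early and heat shock genes to 0.329 for the interferon response. It was not run on the other splits of the libraries. In 30 of the 35 splits of the libraries 7 or more lists passed. The other 19 lists had adjusted p of 0.709 to 0.974 with an estimated correlation. That test was not repeated for the settings below in which some of them passed, except for the cell cycle list. The list of immediate early and heat shock genes stood highest, with a median log2 change 0.70 above that of all genes (camera adjusted p = 1e-09; adjusted p = 0.313 with an estimated correlation). Of its 19 tested members 6 rose and 0 fell, or 8 and 1 adjusted over the list alone. Beside Egr1 and Dusp1, the immediate early genes Ier2 and Junb rose 2.1-fold (adjusted p = 0.00059) and 1.66-fold (adjusted p = 0.0129). The unfolded protein response list lay 0.41 above all genes (camera adjusted p = 4.55e-08; adjusted p = 0.313 with an estimated correlation). Of its 23 members 3 rose and 0 fell, or 8 and 0 adjusted over the list alone. The chaperone genes Hspa5 (log2 change 0.28, adjusted p = 0.481) and Hsp90b1 (0.05, 0.856), named outside the rule, did not pass. Ddit3, a proapoptotic factor of prolonged stress, rose 2.44-fold (adjusted p = 0.00158), Atf3 1.93-fold (adjusted p = 0.0233) and the stress sensor Ern1 1.79-fold (adjusted p = 0.0251). Atf4 was at 358 ± 47 against 255 ± 49.1 RPKM (adjusted p = 0.0661, and 0.0461 without CKO1). Atf3 missed the threshold without CKO2 (adjusted p = 0.0594) or CKO4 (0.0581). Ern1 did so without CKO2 (0.0697), CKO4 (0.0715), WT1 (0.0511), WT2 (0.0585) or WT4 (0.0663).

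Digestive enzyme transcripts made up 59.4 ± 4.0% of reads in CKO and 57.4 ± 1.3% in WT (n = 4 each), a difference of 1.98 points (exact two-sided permutation p = 0.343). Of 36 tested enzymes 3 rose, 4 fell and 29 did not pass, or 4 and 5 adjusted over the list alone. The list median was 0.00 and its mean -0.07, while camera ran upward (adjusted p = 0.14). That test passed without CKO2 (0.03), CKO3 (0.00103) or WT4 (0.0323) and with the length trend removed (0.000228), and turned downward without CKO1 (0.871). With an estimated correlation its adjusted p was 0.709. Spink1, the trypsin inhibitor of acinar cells, fell from 1.35e+03 ± 80.6 to 890 ± 71 RPKM (log2 change -0.60, adjusted p = 0.00551). The amylase gene Amy2a5 (268 ± 94.3 against 566 ± 25.8 RPKM, adjusted p = 0.00541) was lower. So was Amy2b, annotated as an unprocessed pseudogene (125 ± 11.3 against 291 ± 35.6 RPKM, adjusted p = 8.46e-05). The trypsinogen gene Prss3 was higher (2.3e+03 ± 405 against 1.4e+03 ± 199 RPKM, adjusted p = 0.0141). Reads shared with near-identical family members leave the levels of these 3 uncertain. The acinar identity list lay 0.18 above all genes (camera adjusted p = 0.0466; adjusted p = 0.313 with an estimated correlation). Of its 17 members 1 rose and 0 fell, or 1 and 2 adjusted over the list alone. The riser was Fkbp11, a chaperone of the secretory pathway (1.58-fold, adjusted p = 0.00829). The list's call was lost without CKO1 (adjusted p = 0.163), CKO4 (0.0973), WT1 (0.0525) or WT2 (0.122), and also with no filter on low values (0.0748), median centring (0.0966) or totals without the acinar enzymes (0.0537).

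Islet hormone genes lay 0.53 above all genes as a list (camera adjusted p = 2.15e-07; adjusted p = 0.62 with an estimated correlation). Of 14 members 1 rose and 0 fell, or 5 and 1 adjusted over the list alone. Glucagon (Gcg) rose 1.45-fold, from 139 ± 26.8 to 202 ± 28.7 RPKM (adjusted p = 0.0451). It missed the threshold without CKO2, CKO3, CKO4, WT1, WT3 or WT4, with an adjusted p of up to 0.121 without WT1. It also missed it with no filter on low values (0.0936), variances without a trend (0.0518), the replicate number as a block (0.075) and limma-voom (0.0662). Somatostatin (Sst) was at 18.1 ± 0.903 against 12.4 ± 3.63 RPKM (adjusted p = 0.0594, and 0.0201 without WT4). Pancreatic polypeptide (Ppy) was at 6.6 ± 0.702 against 4.13 ± 1.61 RPKM (adjusted p = 0.0733, but 0.0433 without WT4 and 0.0228 with the length trend removed).

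The duct and metaplasia list had a median of -0.45, which put it below all genes (camera adjusted p = 0.031; adjusted p = 0.709 with an estimated correlation). The call was lost without WT4 (adjusted p = 0.0629) and with the length trend removed (0.108). Of 16 members 2 fell and 0 rose, or 10 and 0 adjusted over the list alone. Sox9, a duct and progenitor factor, was at 4.22 ± 1.35 against 8.3 ± 1.25 RPKM (adjusted p = 0.0212). Mmp7 was at 4.22 ± 0.654 against 6.5 ± 1.07 RPKM (adjusted p = 0.0442). The duct keratin Krt19 was at 282 ± 81 against 402 ± 33.7 RPKM (adjusted p = 0.0798, and 0.0323 without CKO3). Sox9 missed the threshold without CKO4 (adjusted p = 0.0577), WT1 (0.0597) or WT3 (0.0538). Mmp7 did so without CKO1, CKO2, CKO4, WT1, WT2, WT3 or WT4, with an adjusted p of up to 0.128 without WT1. It also missed it with no filter on low values (0.0779), limma-voom (0.0667), median centring (0.121), totals without the acinar enzymes (0.071) and the length trend removed (0.0677).

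Monocyte and macrophage genes were lower in CKO as a list, with a median of -0.56 (camera adjusted p = 0.00231; adjusted p = 0.709 with an estimated correlation). Of 21 members 3 fell and 0 rose, or 9 and 0 adjusted over the list alone. The chemokine receptor Ccr2 was at 3.88 ± 1.46 against 7.76 ± 1.98 RPKM (adjusted p = 0.0359). The signalling adaptor Tyrobp was at 22.9 ± 6.65 against 38.7 ± 7.6 RPKM (adjusted p = 0.047). Both missed the threshold without CKO2, CKO4, WT1, WT2, WT3 or WT4. The adjusted p then reached 0.0854 for Ccr2 without CKO4 and 0.109 for Tyrobp without WT2. Tyrobp also missed it with a pseudocount of 0.1 (0.0506). WT2 was the highest library for Ccr2 (10.7 RPKM), Tyrobp (49.8 RPKM) and Lyz1 (6.2 RPKM), and it also held transcripts of fat and of B and plasma cells. Without WT2 the list still passed (camera adjusted p = 0.0122). Lyz1 fell too (log2 change -0.93, adjusted p = 0.0227), except without CKO4 (0.0592), WT1 (0.0597) or WT4 (0.0566), but it shares reads with Lyz2 and its level is uncertain.

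The MHC class II list, of genes that present antigen to helper T cells, had a median of -0.89 (camera adjusted p = 0.00563; adjusted p = 0.709 with an estimated correlation). Of 6 members 2 fell, or all 6 adjusted over the list alone. H2-Aa was at 8.07 ± 2.51 against 20 ± 9.94 RPKM (adjusted p = 0.0349). H2-DMb1 was at 0.997 ± 0.462 against 2.13 ± 0.53 RPKM (adjusted p = 0.0391). WT2 held 34.8 RPKM of H2-Aa against 14.3 to 15.6 RPKM in the other WT libraries. The B cell gene Cd79a, picked after its values were seen, was at 2.67 RPKM in WT2, 1.15 RPKM in WT3 and at most 0.379 RPKM elsewhere. Without WT2 the log2 change of H2-Aa was -0.86 in place of -1.15 (adjusted p = 0.032), and H2-DMb1 missed the threshold (0.0926). H2-Aa missed it without CKO1, CKO2, CKO4, WT1, WT3 or WT4 (0.0575 to 0.0841). H2-DMb1 also missed it without CKO1, CKO2, CKO4, WT1 or WT4 (0.0644 to 0.113). With the length trend removed H2-Aa (0.0644) and H2-DMb1 (0.0719) both missed it, as they did with no filter on low values (0.0755 and 0.0886). H2-DMb1 missed it with limma-voom too (0.0606).

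Of the 13 tested neutrophil genes 0 passed, or 3 lower adjusted over the list alone (camera adjusted p = 0.0964). The list passed without CKO4 (0.00218), WT3 (0.0478) or WT4 (0.0406), and also with no filter on low values (0.0375) or median centring (0.032). With an estimated correlation its adjusted p was 0.709. The calprotectin gene S100a8 was at 9.7 ± 4.49 against 20 ± 6.4 RPKM (adjusted p = 0.0773, and 0.0494 without CKO4). Its partner S100a9 was at 14.6 ± 7.5 against 33.9 ± 11.3 RPKM (adjusted p = 0.0763, but 0.0358 without CKO4 and 0.0459 with variances without a trend). Among 17 cytokine and NF-kB genes 1 rose and 0 fell, or 1 and 1 adjusted over the list alone. The riser was Lif, a cytokine of the IL-6 family (11.3 ± 4.5 against 3.59 ± 1.26 RPKM, adjusted p = 0.0166). The list median was -0.07 while camera ran upward (adjusted p = 0.201, 0.0444 without CKO2 and 0.027 with no filter on low values). Cxcl1, a neutrophil chemokine, was at 2.68 ± 1.92 against 0.971 ± 0.422 RPKM (adjusted p = 0.217).

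In the inflammasome list Pycard, the ASC adaptor, fell from 2.43 ± 0.519 to 0.95 ± 0.104 RPKM (adjusted p = 0.00311). It was 1 of 6 members, with 4 lower adjusted over the list alone (camera adjusted p = 0.167). The list of efferocytosis and alternatively activated macrophage genes had 1 of 12 lower, Arg1, or 2 adjusted over the list alone (camera adjusted p = 0.201). Annexins and formyl peptide receptors had 2 of 13 lower, Anxa1 and S100a10, or 3 adjusted over the list alone (camera adjusted p = 0.191). S100a10, a binding partner of annexin A2, was at 65.2 ± 21.4 against 114 ± 23.1 RPKM (adjusted p = 0.0406). It missed the threshold without CKO1, CKO2, CKO4, WT1, WT2, WT3 or WT4, with an adjusted p of up to 0.0956 without WT1. The replicate number as a block (0.0802), no filter on low values (0.0893), limma-voom (0.0527), median centring (0.0546) and the length trend removed (0.0626) ended its call too.

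In the cytosolic DNA sensing list 1 of 8 members rose and 1 fell, with the same numbers adjusted over the list alone. Camera ran upward (adjusted p = 0.106, and 0.0222 without WT2). Irf3, a transcription factor that drives type I interferon, was at 30.1 ± 1.93 against 21.9 ± 1.16 RPKM (log2 change 0.44, adjusted p = 0.0251). The sensor Ddx41 fell (log2 change -0.50, adjusted p = 0.0266). The CKO values of Irf3 were not whole numbers of reads at any gene length tried. The same was true of CKO values of Irf7, Mavs, Mmp12, Nlrc5, Rbm47, Sting1, Tbk1, Trim41, Usp27x, Wnt5a and Zbp1. Of the 48 CKO values of these 12 genes 39 were not whole, within 0.0001 reads, against 0 of their 48 WT values. All 12 had a higher mean in CKO as deposited. Where lowering 1 of the first 2 significant digits gave exactly 1 whole-read value, that value was put in its place, and 5 of the 12 then had a higher mean in CKO.

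With those replacements the log2 change of Irf3 was -0.31 (adjusted p = 0.166). That of Sting1 was -0.25 in place of 0.34, that of Mavs -0.02 in place of 0.22 and that of Tbk1 0.17 in place of 0.23. The DNA sensing list turned downward (camera adjusted p = 0.556). The levels of these 12 genes in CKO are uncertain. The call of Irf3 was also lost without CKO2 (adjusted p = 0.0674), WT1 (0.0664), WT2 (0.0707), WT3 (0.0519) or WT4 (0.0642). That of Ddx41 was lost without CKO2 (0.0549), CKO4 (0.0581), WT1 (0.0911), WT2 (0.076) or WT3 (0.0531). The interferon response list had 1 of 21 members lower, Irf1, and 0 higher, with the same numbers adjusted over the list alone (camera adjusted p = 0.911). Irf1 missed the threshold without CKO1, CKO2, CKO4, WT1, WT2, WT3 or WT4, with an adjusted p of up to 0.0978 without WT2.

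**Figure D2:**
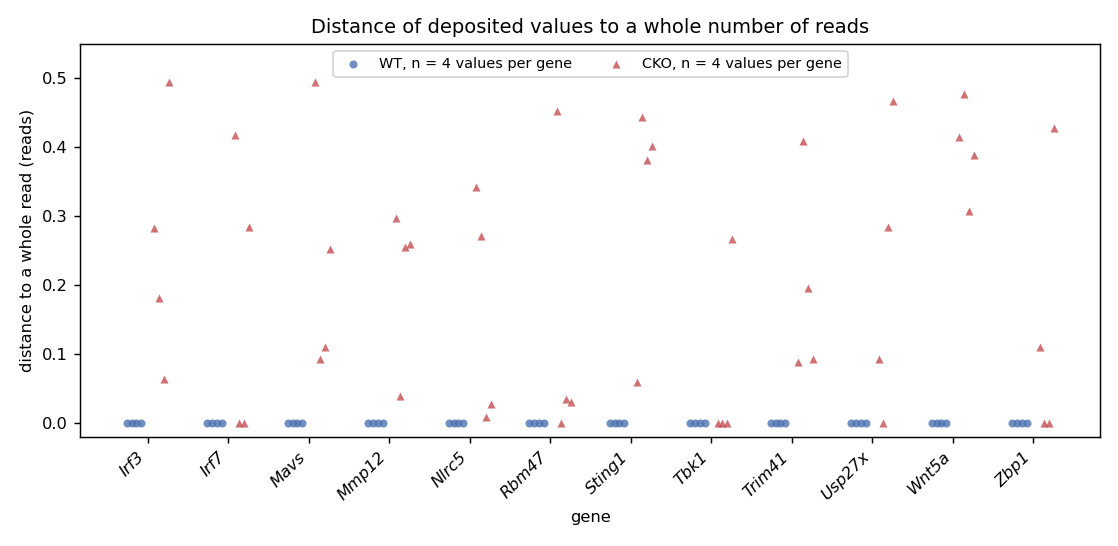
Distance of each deposited value to the nearest whole number of reads (vertical axis, reads) for the 12 genes named on the horizontal axis, at the gene length that makes their WT values whole, with 4 WT values (circles) and 4 CKO values (triangles) per gene. All 48 WT values lie at 0, and 39 of the 48 CKO values do not.

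Nfe2l2, which encodes the antioxidant regulator Nrf2, rose 2.55-fold (32.3 ± 7.11 against 12.6 ± 2.11 RPKM, adjusted p = 0.0011). In its list of 18 genes 5 fell, or 6 adjusted over the list alone, and 1 rose by either count (camera adjusted p = 0.0851). The list passed without CKO2 (0.0422), CKO4 (0.0107), WT2 (0.0101) or WT3 (0.0478), and also with no filter on low values (0.0165) or median centring (0.0367). Among those that fell were the antioxidant enzyme Gpx1 (log2 change -0.50, adjusted p = 0.0222), G6pdx, which supplies NADPH (-0.70, 0.0197), and Gclm, of glutathione synthesis (-0.57, 0.0233). Gpx1 missed the threshold without CKO2, CKO4, WT1, WT2 or WT4 (0.0505 to 0.0674). G6pdx missed it without CKO4 (0.053), WT1 (0.0664) or WT2 (0.0537), and Gclm without WT1 (0.0749), WT3 (0.059) or WT4 (0.061).

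Of 15 cell death genes 1 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.911). Bbc3, which encodes the proapoptotic protein PUMA, rose 4.13-fold (adjusted p = 0.0011). The proapoptotic genes Bax (log2 change -0.52, adjusted p = 0.0255) and Bcl2l11 (-0.65, 0.0276) fell. Bax missed the threshold without WT1, WT2, WT3 or WT4 (0.0575 to 0.0691) and Bcl2l11 without CKO2, CKO4 or WT1 (0.0637 to 0.0749). In the lysosome and autophagy list 3 of 21 fell, or 4 adjusted over the list alone (camera adjusted p = 0.106, and 0.0264 with no filter on low values). Ctsl, which encodes cathepsin L, fell from 568 ± 37.6 to 282 ± 69.5 RPKM (adjusted p = 0.00551). Grn fell with a log2 change of -0.47 (adjusted p = 0.0179), except without WT1 (0.063) or WT3 (0.0524). Vmp1 fell with a log2 change of -0.52 (adjusted p = 0.0215), except without WT1 (0.0511) or WT4 (0.0567). The acute-phase and pancreatitis stress list had 3 of 17 higher, Egr1, Atf3 and Lif, also adjusted over the list alone. Its median was -0.25 while camera ran upward (adjusted p = 0.167). The acute-phase gene Saa3 was at 40 ± 25.3 against 164 ± 138 RPKM (adjusted p = 0.0931). It passed without CKO4 (0.047), with variances without a trend (0.0356) and with limma-voom (0.0484).

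Most cell cycle genes (17 of 23) lay below the filter. Of the 23 genes 13 were higher in every CKO library than in every WT library and 2 were lower in every CKO library. Of all 14712 genes with at least 10 reads 2.6% were higher and 13.5% lower in every CKO library. Top2a had 168 to 244 reads in each CKO library and 2 to 63 in each WT library, and Plk1 had 34 to 43 and 0 to 8. The proliferation marker Mki67 had 125 to 185 and 3 to 74. Cdk1 was at 0.267 ± 0.0279 against 0.272 ± 0.0879 RPKM. These 4 were named after their values were seen. With no filter on low values the list passed upward (camera adjusted p = 2.94e-12; adjusted p = 0.348 with an estimated correlation). Without the filter 9 members were higher and 2 lower, or 14 and 2 adjusted over the list alone. Fry, run without the filter on this list alone, gave an unadjusted p of 0.00157 for a shift in 1 direction. With the filter 6 members were tested, 1 higher and 2 lower, the same adjusted over the list alone, and the test ran downward (camera adjusted p = 0.543). The cell cycle inhibitor Cdkn1a rose 2.18-fold (172 ± 34.3 against 78.9 ± 22.4 RPKM, adjusted p = 0.0152). The DNA replication genes Mcm6 (2.8 ± 0.339 against 5.18 ± 0.988 RPKM, adjusted p = 0.0139) and Pcna (9.75 ± 1.25 against 15.4 ± 1.39 RPKM, adjusted p = 0.0141) fell.

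**Figure D3:**
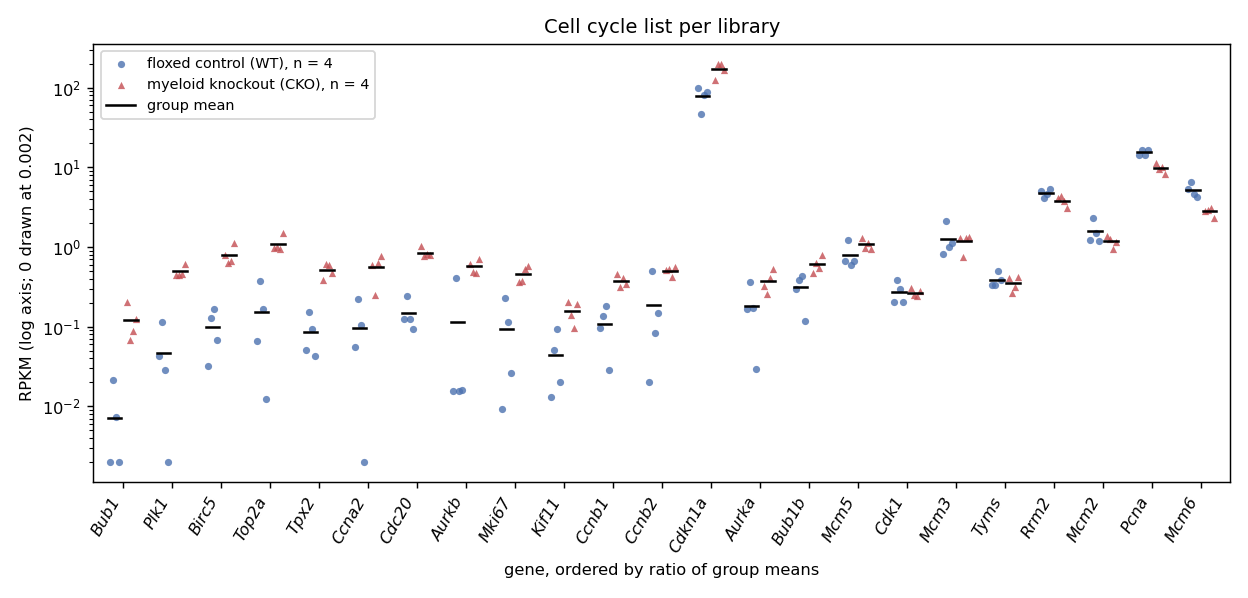
RPKM (log axis, with 0 drawn at the foot of the axis) of the 23 cell cycle genes, ordered by the ratio of group means, with 1 point per library (circles WT, triangles CKO, n = 4 each) and a black bar at each group mean. The 13 genes with no overlap and higher CKO values sit mostly below 1 RPKM, apart from Cdkn1a at 172 against 78.9 RPKM.

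Some brain transcripts, named here after their values were seen, were lower in CKO. Snap25 had 99 to 158 reads in each WT library and 2 to 22 in each CKO library, Camk2a 124 to 183 and 1 to 11, and Hpca 70 to 111 and 0 to 1. Uchl1, in the list of muscle, nerve and mesothelium, fell by 0.70 on the log2 scale (adjusted p = 0.0296), and missed the threshold without CKO4 (0.0771), WT1 (0.0733), WT3 (0.0688) or WT4 (0.0696). That list had 4 tested members, 2 of them lower (1 higher and 2 lower adjusted over the list alone), too few for a list test. Of 5 red cell and platelet genes 2 were lower, or 3 adjusted over the list alone (camera adjusted p = 0.0819, but 0.0148 without CKO3, 0.00736 without WT1, 0.0367 with median centring and 0.042 with the replicate number as a block). These 2 were the globins Hba-a2 and Hbb-bt, which share reads with near-identical copies and are uncertain. Without CKO2, CKO4, WT2, WT3 or WT4 both missed the threshold (adjusted p 0.065 to 0.0955), as did Hbb-bt without WT1 (0.0844). Of 13 endothelial genes 1 was lower, Kdr, the main VEGF receptor (1.1 ± 0.211 against 2.1 ± 0.487 RPKM, adjusted p = 0.0278), also adjusted over the list alone (camera adjusted p = 0.911). Of 8 fat genes 1 was lower, Lpl (5.55 ± 1.38 against 9.58 ± 1.99 RPKM, adjusted p = 0.0323), also adjusted over the list alone (camera adjusted p = 0.276), and WT2 held 9.12 RPKM of the fat transcript Adipoq against 1.2 RPKM or less in the other libraries. Kdr missed the threshold without CKO2, CKO4, WT1 or WT2 (adjusted p 0.0671 to 0.083), and Lpl without CKO1, CKO2, CKO4, WT1, WT2 or WT4 (0.0506 to 0.088).

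Of 24 fibroblast and matrix genes 0 passed, also adjusted over the list alone. The median was -0.04 while camera ran upward (adjusted p = 0.101, and 0.03 without CKO2 and 0.000138 without WT2). Of 35 ribosomal protein genes 1 was lower, Rps19, and 0 adjusted over the list alone (camera adjusted p = 0.334, and 0.0264 without WT3). Rps19 missed the threshold without CKO1, CKO2, CKO4, WT1, WT2 or WT4, with an adjusted p of up to 0.111 without WT1. Of 9 clock genes Nr1d1 and Nr1d2 (log2 change -0.56, adjusted p = 0.0417) fell and Per1 rose 1.84-fold (adjusted p = 0.0347), with the same counts adjusted over the list alone. The clock median was 0.13 and the mean -0.06, with camera upward (adjusted p = 0.183). The mixed test of fry, which counts changes either way, gave an adjusted p of 0.00125. Nr1d2 missed the threshold without CKO1, CKO2, CKO4, WT1, WT2, WT3 or WT4 (up to 0.107 without CKO4), and Per1 without WT1, WT2, WT3 or WT4 (0.0503 to 0.115).

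Too few members were tested for a list test of T and natural killer cells (1), B and plasma cells (1), gut and liver (1), mast cells, eosinophils and dendritic cells (2) and sex-linked genes (2). None of those members passed over all genes. Adjusted over the list alone, only Ttr, from the gut and liver list, passed, as higher (adjusted p = 0.0127, which with 1 member is its unadjusted p). Which cells made it the table does not tell. Short genes fell more than long ones. The median log2 change was -0.25 in the tenth of genes with the shortest length and -0.02 in the tenth with the longest. The Spearman correlation of length with log2 change was 0.30 across 8505 genes, which are not independent replicates.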

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

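The tests of the values that were not whole reads were chosen after that result was seen; the tests of the brain transcripts and of the stress gene lists were fixed after those patterns were noticed but before their own results were seen, and the splits of the libraries were fixed before the data were examined.

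Of the 35 splits of the 8 libraries into 4 and 4, only the real split (1 of 35) gave as many as 610 changed genes, and the highest other split gave 1 gene. No result can be rarer than 1 of 35 here. The other splits mix CKO and WT libraries on each side, so a group difference adds to their spread and lowers their counts. The splits make chance less likely for that count without excluding it. The same held for the 64 genes changed at least 2-fold (1 of 35 splits, with 1 gene in the highest other split). For the 7 lists past the threshold chance cannot be excluded: 30 of the 35 splits gave 7 or more, and the highest other split gave 16. Other splits calling more lists than the real split points to genes that vary together between samples within each group.

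In the 12 genes whose CKO values were not all whole reads, 39 of 48 CKO values and 0 of 48 WT values departed from whole reads. Limited print precision or an unusual gene length would affect both groups alike, and a single length made the WT values of all 12 genes whole while 0 of the 12 had a length that did so for CKO alone. A candidate explanation is that single digits differ from those first computed. Lowering 1 of the first 2 significant digits made 37 of the 39 values (94.9%) whole, against 0.2% of 19500 random values. To check this step, the first digit of 381 deposited CKO1 values was raised by 1, and lowering restored 99.7% of them. That check shows only that the step can undo such a change, not how the values arose. The unnamed column, outside the main measurement, equals the row of Tbk1 in 7 of its 8 numbers and differs in CKO4, with 4.471 where the row holds 5.471, and 4.471 RPKM is a whole number of reads. How these values arose, and which version was measured, the table does not tell, and no biological explanation was tested.

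Some brain transcripts were higher in the WT libraries than in CKO, while others, such as Camk2b (9 RPKM in WT and 6.74 RPKM in CKO) and Syn1 (1.56 and 1.67 RPKM), did not separate the groups. Of 43 further brain genes with at least 10 reads, from a list written before they were looked at, 19 (44.2%) were higher in every WT library and 0 lower, against 13.5% and 2.6% of all 14712 such genes, which may reflect brain RNA or reads in the WT libraries; 4 of the 43 reached 1 RPKM in CKO pancreas, none of them among the 19, and 0 of the 43 were in another list. Snap25 was at 1.65 RPKM and Hpca at 1.44 RPKM in WT, and the labels name no sort. The test of peripheral nerve could not decide: 1 of 8 Schwann cell genes (12.5%) separated the groups, above the bound of 10% set beforehand for arguing against it. That share was close to the 13.5% of all genes, and 8 genes are few. A trend on gene length is argued against since 78.9% of the 19 still separated once it was removed. Brain material or reads entering at dissection, library preparation or sequencing of the WT samples, peripheral nerve, and an effect of the genotype, which was not tested, stay open.

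The immediate early and unfolded protein response lists stood above all genes in CKO. A trend on gene length is argued against, since the lists kept 104% and 93.6% of their median difference from all genes once it was removed (camera adjusted p = 1.22e-10 and 3.14e-09 at the preset correlation, while before the removal both had 0.313 with an estimated correlation and 0.0887 with fry). Another hour or way of tissue collection may contribute, since immediate early genes respond to handling. Camera asks for a shift of the clock list in 1 direction (adjusted p = 0.183), while Nr1d1 and Nr1d2 fell and Per1 rose. It could not show changes that run both ways. The mixed test of fry, which counts them, gave an adjusted p of 0.00125 for the clock list. Other lists passed that mixed test too, such as the immediate early list (3.55e-08). Collection and genotype cannot be told apart here, as the labels give no collection times. As small a camera p arose in 4 of the 35 splits for the immediate early list and in 5 for the unfolded protein response list. The other lists past the threshold had higher counts. These were 6 for MHC class II, 7 for duct and metaplasia, 11 for islet hormones, 13 for acinar identity and 14 for monocytes and macrophages. An effect of the genotype stays open and untested.

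In 14 of the 178 groups of 4 libraries, those of 89 genes taken from the rule for named genes (not all of them described in the report), the highest or the lowest library stood apart from the other 3 by more than the critical value of Dixon's ratio, where chance gives 5%, or 8.9 groups, and 7 of the 14 were in WT2. In WT2 these were H2-Aa at 34.8 RPKM, Cd74 at 99.5 RPKM, Saa3 at 369 RPKM, Spink1 at 1.47e+03 RPKM and Zbp1 at 3.63 RPKM, each the highest of its group, and Atf4 at 182 RPKM and Gclm at 8.79 RPKM, each the lowest. Among the other WT libraries, Nr1d1 reached 39.1 RPKM in WT3. Among the CKO libraries, Amy2a5 reached 409 RPKM in CKO1, Fkbp11 77 RPKM in CKO4, Saa3 77.5 RPKM in CKO4 and Bcl2l11 1.03 RPKM in CKO3, while Ern1 was lowest at 14.2 RPKM in CKO1 and Spink1 at 784 RPKM in CKO2.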

How the results depend on the processing

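Median centring, totals without acinar enzymes, removal of the length trend, leaving out the 12 genes without whole reads and lowering 1 digit of their values were chosen after the data were seen; the other alternatives were not. The edgeR and DESeq2 alternatives, meant for a table of counts, were not run on the recovered reads, nor was the acinar share without mitochondrial genes, of which there are 0. The acinar enzyme share difference ran from 0.84 to 3.61 points over the 8 omissions of 1 library, and none reached the threshold. The number of changed genes stayed within 1.5 times of 610 in all settings except omissions, where it ran from 185 without WT1 to 686 without CKO3 (228 without CKO2, 267 without CKO4, 245 without WT2, 297 without WT3, 254 without WT4). With 1 library fewer the test has less power, and the cause was not tested further. A similar count did not mean the same genes. Of the 610 genes, 280 passed with no filter on low values, 379 with median centring, 412 with limma-voom and 431 with the length trend removed. With a pseudocount of 0.1 it was 555, and with variances without a trend 597. Higher genes ran from 47 without CKO2 to 242 without CKO1, lower genes from 130 without WT1 to 600 without CKO3. Centring gave 345 higher and 260 lower, totals without acinar enzymes 228 higher, and limma-voom 323 lower. At least 2-fold changes numbered 142 with a pseudocount of 0.1 and 149 with limma-voom, which shrink ratios of low values less. With the replicate number as a block, 548 genes passed (110 higher, 438 lower). Gcg, Gpx1, Insig1, Irf3, Per1, Rps19 and S100a10 then missed the threshold, while Anxa4, Ccl7, Cd74, Msr1 and Retnla passed. The unpaired test was set beforehand, since the labels do not mark pairs. Same-number libraries, checked later, correlated at -0.32 to 0.14 in their deviations from the group means, which gave no reason to pair them. Anxa1 kept its direction but missed the threshold without the filter (-0.73), with limma-voom (-0.83), centring (-0.61), totals without acinar enzymes (-0.66) and the length trend removed (-0.64), and ran from -0.86 without WT3 to -0.54 without WT2. The lists past the threshold numbered 11 without the filter, 0 with an estimated correlation, 0 with fry, and 6 to 11 over the omissions.

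Of 88 other genes taken from the rule for named genes, not all of them described in the report, 64 passed, 31 of them under every alternative that tested them (Gdf15, Bbc3 and Per1 did not pass the filter when any CKO library was left out), and 33 missed the threshold in at least 1 omission. With no filter 23 missed it: Atf3, Bcl2l11, Ccr2, Ern1, Gcg, H2-Aa, H2-DMb1, Hba-a2, Hbb-bt, Insig1, Irf1, Kdr, Lpl, Lyz1, Mmp7, Nr1d2, Per1, Rps19, S100a10, Sox9, Tcim, Tyrobp and Uchl1. With the length trend removed 12 missed it: Bax, Gpx1, H2-Aa, H2-DMb1, Hba-a2, Hbb-bt, Mmp7, Per1, Rps19, S100a10, Tyrobp and Uchl1, while Atf4, Msr1, Ppy and Sst passed. With limma-voom 10 missed it: Gcg, H2-DMb1, Hba-a2, Hbb-bt, Mmp7, Nr1d2, Rps19, S100a10, Tyrobp and Uchl1, while Saa3 passed. With centring 9 missed it: Hbb-bt, Insig1, Mmp7, Rps19, S100a10, Tcim, Tyrobp, Uchl1 and Vmp1, while Atf4, Irf7 and Sst passed. Totals without acinar enzymes ended the calls of Hbb-bt, Mmp7 and Rps19 and began that of Atf4. Lowering 1 digit turned Irf3 to -0.31, Sting1 to -0.25, Mavs to -0.02, Trim41 to -0.15 and Zbp1 to -0.11, and the DNA sensing list downward (adjusted p = 0.556). Uncalled lists changed direction as follows, and the cause was not tested: with fry, which does not compare with other genes, acinar enzymes (0.44), fibroblasts (0.923), NF-kB (0.912) and clock (0.923); with a filter at 1 CPM, endothelium (0.924), interferon (0.929) and cell death (0.847); with the length trend removed, interferon (0.865) and ribosomal proteins (0.14). Over the omissions adjusted p ran from 0.00103 to 0.871 for acinar enzymes (turning without CKO1), 0.48 to 0.967 for endothelium (CKO2, WT2), 0.0444 to 0.931 for NF-kB (CKO4), 0.195 to 0.985 for interferon (CKO1, WT2), 0.297 to 0.979 for cell death (WT4) and 0.0264 to 0.637 for ribosomal proteins (WT4). The cell cycle list turned upward and passed without the filter (2.94e-12) and at 1 CPM (0.000256), which admit its genes of low level, but not without the filter and with an estimated correlation (0.348). At recovered totals of 30469002 to 34359802 reads per library, genes near 0.087 RPKM at 1 kb rest on 3 reads.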

Other observations

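The values in this part belong to no planned comparison, and the genes were picked after their values were seen. Nos2, the inducible nitric oxide synthase of activated macrophages, had a mean of 0.151 RPKM in CKO and 0.0128 RPKM in WT, with 12, 16, 22 and 36 reads in CKO1 to CKO4 and 1, 5, 0 and 1 reads in WT1 to WT4. Ube2c, which drives exit from mitosis, was at 1.28 RPKM in CKO and 0.238 RPKM in WT (log2 change 0.88, adjusted p = 0.00119). With no filter on low values, the cell cycle list had an unadjusted camera p of 9.47e-14 in the real split and 1.14e-13 in the closest of the other 34 splits, so these were nearly tied. With an estimated correlation its adjusted p was 0.348.

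WT2 held transcripts of fat and of B and plasma cells. Adipoq was at 9.12 RPKM in WT2 and at most 1.2 RPKM elsewhere, and Cfd at 77.5 RPKM, with 9.99 RPKM in CKO4 the next. Jchain, the joining chain of secreted antibodies, was at 7.21 RPKM in WT2 and 2.58 RPKM in WT3, and Cd79a, of the B cell receptor, at 2.67 and 1.15 RPKM. The granule gene Ngp of immature neutrophils was at 1.21 RPKM in WT2 and 1.38 RPKM in WT3 and at most 0.136 RPKM in the other libraries. CKO4 held the liver and gut transcripts Apoa1 at 3.43 RPKM and Fabp1 at 1.48 RPKM, against at most 0.0592 and 0.243 RPKM elsewhere. The Y-linked gene Ddx3y was present in all 8 libraries, at 1.63 to 2.41 RPKM.

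Counts of every 2 libraries within a group differed by far more than counting error, with a chi-square per degree of freedom of 21.2 to 105 over the 12 pairs, so none of the 12 were repeated runs of the same library.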
